A study of Mus musculus with 26 samples.

How the data were processed

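Lungs of BALB/c mice were profiled on a gene-level Affymetrix array at embryonic day 14.5 (E14.5), at E18.5 and at postnatal day 40 (P40). Per the series' design text, pregnant dams breathed a dose of fine particulate matter (PM2.5, airborne particles up to 2.5 µm across) equivalent to 600 µg/m3 for 1 h daily from E5.5, or filtered air. Offspring carried to P40 stayed in the same arm after birth, with no cross-over. There were 4 control and 4 exposed samples at E14.5, 4 and 4 at E18.5, and 5 and 5 at P40. Per the labels' protocols, fetal lungs were dissected from dams and the right lungs of P40 mice were collected after a lung function assessment. Total RNA was isolated with the RNeasy Mini Kit and 100 ng per sample was amplified and labelled with the Ambion WT Expression Kit. The labels give neither the sex of the animals nor the dam or litter of a fetus, so the p-values measure the spread between samples, whose independence as animals or litters is not stated.

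The deposited values are log2 intensities, made by RMA (background correction, quantile normalization between arrays and summarization per probe set) in Affymetrix Expression Console per the submitters' processing notes. Software versions, the probe set library and a genome build are not given in the sources used here, so no coordinates are printed. The values ran from 1.26 to 14.1, and the medians of the 26 arrays lay between 6.35 and 6.50. No pair of arrays held identical values (0 pairs). An array has no sequencing depth; the number of arrays limits the precision.

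The value table holds 41345 probe sets. The platform's gene table lists 25341 of them, of which 23521 carry 1 gene symbol and 1820 carry several; 16004 are not listed. Symbols were used as that table gives them; 23328 probe sets matched the reference gene table by Entrez identifier (that table names the GRCm38.p6 assembly and served for names only), and 0 symbols were updated through it. Probe sets with 1 symbol were used, and for each of 22180 genes the probe set with the highest mean over all 26 arrays was kept; 1082 genes had more than 1. The genes with the lowest mean (a share of 0.25, below 5.51 on the log2 scale) were left out as dim, which left 16635 genes tested. The 24710 probe sets outside that selection were tested apart.

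Differences were fitted with limma (lmFit and eBayes with trend off and robust off) and p-values were two-sided and adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Exposed and control lungs were compared at each stage with the arrays of that stage only. Whether the exposure difference changed between stages was tested as an interaction in a fit of all 26 arrays in 6 groups. That fit shares its estimate of the spread over all stages, also over the stage that is not compared. A difference common to the 3 stages was fitted as exposure plus stage. Normal development was tested in the 13 control arrays, E18.5 against E14.5 and P40 against E18.5, with a second count at a fold of 2. Errors beside log2 differences are standard errors of the limma coefficient; errors beside group means are standard deviations.

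Gene lists (56, covering lung and blood cell types, neighbouring tissues, responses to air pollution and developmental pathways) were written from general knowledge; 55 had at least 5 tested genes, with 1057 members tested. Each was tested with limma's camera at its preset correlation of 0.01, and also with camera at the estimated correlation and with fry, adjusted over the 55 lists of a comparison. Members were also adjusted over the list alone. The comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named up to 12 rises and 12 falls that passed, or the 12 genes with the smallest p where fewer than 12 passed, up to 4 members of each list that passed camera, list members that passed, and 9 genes in every exposure comparison at a stage (Cyp1a1, Cyp1b1, Nqo1, Hmox1, Mt1, Mt2, Sftpc, Scgb1a1 and Xist). Predicted gene models, small RNAs and multigene receptor or immunoglobulin segments were counted but not named. The exception is the flagged list of interaction genes, which gives every gene that passed, the gene model Gm13315 included.

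Scores per array were means of a list's genes: liver, heart muscle, skeletal muscle, erythroid, endothelial and proliferation. A sex score was Xist minus the mean of 3 Y-linked genes. A developmental position score used genes that changed with stage in the control lungs. Scores were compared between arms at each stage by exact permutation of the arms (two-sided), 30 tests in all with Benjamini-Hochberg adjustment; the smallest p these allow is 0.0286 with 4 against 4 arrays and 0.00794 with 5 against 5. Alternatives tried were no filter on dim genes, leaving out the lower share of 0.5 by mean, trend and robust eBayes, array quality weights, quantile normalization again, centring on array medians, the mean of all probe sets of a gene, every probe set tested, a fold of 1.5 as well, the sex score as covariate, all 26 arrays in the stage fits, a block for the replicate number, and leaving out each array in turn. A liver score and a muscle score (heart and skeletal lists) as covariates were added after the data were seen. Groups were also rearranged, over all splits or 100 drawn at random.

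The fits were tested on simulated data in which 67, 67 and 66 genes were given log2 changes of 0.5, 1 and 2 among 16635 genes with the design of each comparison. At a change of 1, 91.0% were recovered for E14.5, 74.6% for E18.5, 89.6% for P40, 85.1% for the E18.5 against E14.5 interaction, 83.6% for P40 against E18.5, 82.1% for P40 against E14.5, 100% for the common difference, and 86.6% and 95.5% for the developmental comparisons. At 0.5 the recovery was 49.3%, 29.9%, 49.3%, 28.4%, 23.9%, 28.4%, 89.6%, 55.2% and 62.7% in that order. The false calls per comparison were 10, 4, 5, 8, 5, 7, 9, 9 and 9. The endothelial list, shifted by 0.3 in all its members, was called by camera in each comparison; the simulated genes were independent of each other, unlike real genes. Work was done in R 4.3.3 with limma 3.58.1, and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 for the figures.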

Results

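Gene expression was measured in 26 mouse lungs: 4 control and 4 exposed lungs at E14.5 (pseudoglandular stage, when airways branch), 4 and 4 at E18.5 (saccular stage, just before birth), and 5 and 5 at P40 (alveoli formed). The exposed animals came from dams that breathed PM2.5 from E5.5, and at P40 they had also been exposed after birth. Values are log2 RMA intensities, each gene by 1 probe set, with 16635 genes tested. Differences are exposed minus control with the standard error from limma, group means carry the standard deviation, and adjusted p-values are over all genes tested unless said otherwise.

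Stage set the arrays apart. The first principal component held 72.2% of the variance and ordered the stages from E14.5 to P40, and the next held 12.6%. Arrays of the same group correlated at a mean r between 0.972 and 0.989. Exposed and control lungs of the same stage overlapped on both components. At E18.5 exposed arrays 1, 2 and 3 lay nearer to E14.5 on the first component (-26.5, -10.4 and -28.7) than any control array (-8.65 to 8.78), and at E14.5 exposed arrays 1 and 4 lay nearer to E18.5 (-66.2 and -68.5) than any control array (-84.5 to -78.1).

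**Figure D1:**
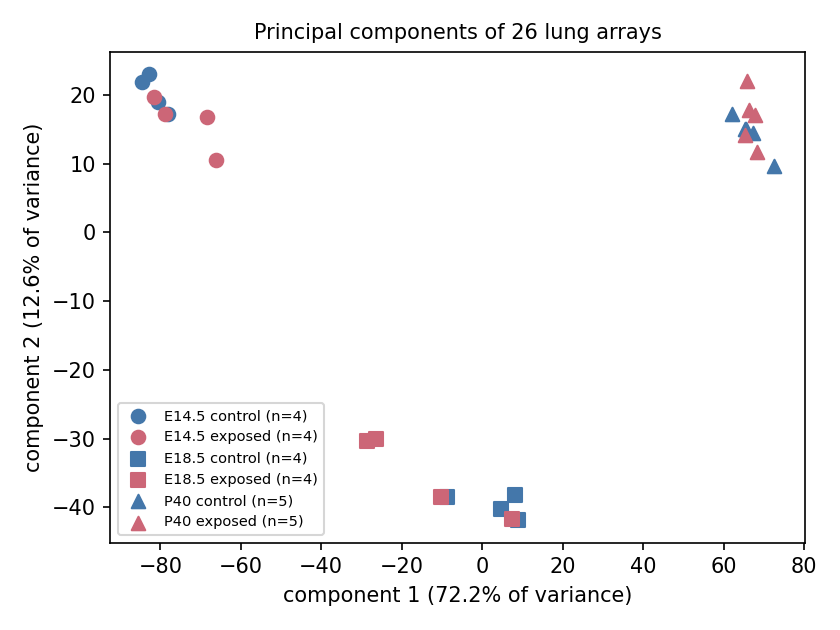
Each point is 1 array, placed by its scores on the first principal component (x axis, 72.2% of the variance) and the second (y axis, 12.6%), both without units; the marker gives the stage and the colour the arm. The 3 stages form separate clouds, and some exposed arrays at E14.5 and E18.5 lie toward the other fetal stage.

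The comparison at E14.5 asked what 9 days of maternal exposure had done to the fetal lung while its airways were branching. Endothelial and distal epithelial genes lay higher in exposed lungs and muscle genes lower, but no single gene passed (0 higher and 0 lower by limma). Without adjustment 1269 genes had p under 0.05, where 0.05 of the tested genes is 832. With the arms rearranged, 4 of 35 splits, the real one included, gave at least as many. Limma with trend and robust moderation also called 0 genes. The fit of all 26 arrays called 24 genes, 5 higher and 19 lower. The endothelial gene Cyyr1, whose protein is a small membrane protein of unclear function, averaged 8.98 ± 0.09 in control and 9.52 ± 0.16 in exposed lungs, a difference of 0.54 ± 0.10 (n = 4 and 4, adjusted p 0.581).

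The smallest adjusted p at E14.5 was 0.144, for a gene model that is counted but not named. Genes that follow had an adjusted p of 0.581, among them Ccr2 (0.78 ± 0.13), the chemokine receptor of recruited monocytes, Muc5b (0.58 ± 0.11), a gel-forming airway mucin, and Clec1a (0.63 ± 0.12), a lectin of endothelial cells. The calcium channel Trpc1 differed by 0.34 ± 0.06, the ion channel Trpm6 by 0.73 ± 0.12, C87198 by 0.74 ± 0.11, Sag by 0.37 ± 0.07 and Pkn3 by 0.36 ± 0.07. Follistatin (Fst), which binds activins, was lower by point estimate (-0.79 ± 0.15), as were Lhfpl1 (-0.62 ± 0.12) and Gnb3 (-0.47 ± 0.09).

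Camera at its preset correlation called 23 of 55 gene lists at E14.5, 12 higher and 11 lower. With the correlation estimated from the arrays the smallest adjusted p was 0.529, and neither that setting nor fry called a list (0 and 0). Skeletal muscle genes lay lowest: 16 of 17 were below control, with a median of -1.10 (camera 6.21e-12, estimated 0.529), and 12 of them fell when adjusted over the list alone. They included Myl1 (-1.10 ± 0.26), Tnni2 (-1.19 ± 0.35) and Acta1 (-1.42 ± 0.43). Heart muscle genes followed, with 28 of 29 below control and a median of -0.63 (camera 3.92e-06, estimated 0.625); 0 passed over the list alone. The skeletal score averaged 8.36 ± 0.69 in control and 7.35 ± 0.34 in exposed lungs, and its exact permutation p was 0.0857.

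Vessel and epithelial lists at E14.5 went the other way. Of 25 endothelial genes, 24 lay above control with a median of 0.25 (camera 9.25e-11, estimated 0.529), and 2 rose when adjusted over the list alone; the tight junction gene Cldn5 differed by 0.49 ± 0.10, VE-cadherin (Cdh5) by 0.21 ± 0.06 and Sox18 by 0.31 ± 0.10. Genes of alveolar type 1 cells, which form the gas exchange surface, had a median of 0.31 with 16 of 18 above control (camera 3.2e-06, estimated 0.529); 1 rose over the list alone, and Gprc5a differed by 0.68 ± 0.17. Surfactant and alveolar type 2 genes had a median of 0.71 with 17 of 20 above control (camera 2.27e-05, estimated 0.543) and 0 passing over the list alone; Muc1 differed by 1.13 ± 0.31, Lamp3 by 1.31 ± 0.43 and surfactant protein C (Sftpc) by 1.00 ± 0.49 (adjusted p 0.701). Club cell genes had a median of 0.36 (camera 0.000483, estimated 0.543), and the secretoglobin Scgb1a1 differed by 2.80 ± 1.80 (adjusted p 0.783). With the muscle score as covariate, 6 lists passed in place of 23: endothelial, alveolar type 1, skeletal muscle, heat shock and basal cell genes in the same direction, and heart muscle genes with their direction turned. The muscle score is made of the heart and skeletal lists, so in that fit their mean differences must be opposite. The calls of those lists there are therefore no result about exposure. Exposed arrays 1 and 4, which lay toward E18.5, had the highest endothelial scores (10.1 and 9.88, control 9.48 to 9.70).

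Smaller groups at E14.5 included imprinted growth genes, with a median of -0.14, 14 of 15 below control (camera 2.2e-05, estimated 0.529), 1 of which fell over the list alone. The cell cycle inhibitor Cdkn1c in that list differed by -0.48 ± 0.11. Glia and neuron genes had all 17 members below control and a median of -0.23 (camera 0.000635, estimated 0.529), with Fabp7 at -0.71 ± 0.19. Retinoic acid genes had a median of -0.25 (camera 0.00396, estimated 0.529), with Crabp2 at -0.98 ± 0.28. Type 2 immunity and mucus genes had a median of 0.23 (camera 0.00396, estimated 0.529); 2 rose over the list alone, and Muc5ac differed by 0.43 ± 0.12.

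Genes that answer to combustion products differed little at E14.5. Xenobiotic response genes had a median of 0.04 (camera 0.482), oxidative stress genes did not pass (0.86), and metal response genes had a median of 0.02 (0.871). Cyp1a1, the classic target of the aryl hydrocarbon receptor, differed by 0.13 ± 0.16 (adjusted p 0.927), Hmox1 by 0.17 ± 0.17, Nqo1 by 0.02 ± 0.09, Mt1 by 0.11 ± 0.34 and Mt2 by -0.07 ± 0.32. Cyp1b1 differed by -0.77 ± 0.25 (adjusted p 0.581).

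At E18.5 the question was the same for lungs close to birth, after 13 days of exposure. Serpina6, which encodes corticosteroid-binding globulin and is made mainly in liver, rose from 5.27 ± 0.14 in control to 7.08 ± 0.11 in exposed lungs, by 1.81 ± 0.10 (n = 4 and 4, adjusted p 0.000328, probe set 17283573). Unadjusted p was under 0.05 for 1219 genes, where 0.05 of the tested genes is 832. With the arms rearranged, 7 of 35 splits, the real one included, gave at least as many. Serpina6 was the only gene past the threshold by limma (1 higher, 0 lower), with or without trend and robust moderation. In the fit of all 26 arrays its adjusted p was 0.264 and Cfi was called in its place; leaving out the dimmer share of 0.5 of the genes removed it from the test. Serpina6 was high at E14.5 in both arms (9.52 ± 1.81 in control, 8.86 ± 1.34 in exposed) and low at P40 (5.51 ± 0.08 and 5.76 ± 0.29).

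Camera called 22 lists at E18.5, 4 higher and 18 lower; with estimated correlation it called 0 (smallest adjusted p 0.487), and fry called 0. Liver genes as a group were higher in exposed lungs: 18 of 19 lay above control, with a median of 1.74 (camera 2.39e-10, estimated 0.571), and 11 rose when adjusted over the list alone. Albumin (Alb) went from 7.29 ± 1.18 to 11.60 ± 1.61, a difference of 4.31 ± 0.81, alpha-fetoprotein (Afp) differed by 3.61 ± 0.76, fetuin (Ahsg) by 3.38 ± 0.90 and Apoa1 by 2.10 ± 0.64, each at an adjusted p of 0.612. The liver score averaged 6.17 ± 0.17 in control and 7.88 ± 1.33 in exposed lungs, and the exact permutation p of 0.0286 is the smallest that 4 against 4 arrays allow (0.286 adjusted over 30 tests). Complement factor I (Cfi), also abundant in liver, differed by 1.55 ± 0.24, Habp2 by 0.80 ± 0.15 and Mat1a by 0.90 ± 0.18 (adjusted p 0.612). With the liver score as covariate 834 genes passed, 439 higher and 395 lower, Serpina6 among them at 1.75.

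Endothelial genes at E18.5 lay lower in exposed lungs. Their median was -0.25, with 23 of 25 below control (camera 5.68e-12, estimated 0.487), and 5 fell over the list alone. Icam2, an adhesion molecule of endothelium, differed by -0.59 ± 0.10, Cyyr1 by -0.48 ± 0.12, the VEGF receptor Kdr by -0.32 ± 0.10 and von Willebrand factor (Vwf) by -0.39 ± 0.11, all at an adjusted p of 0.612. Pericyte genes lay below control in 14 of 14 cases with a median of -0.25 (camera 8e-07, estimated 0.571), Higd1b among them at -0.60 ± 0.18; 0 passed over the list alone. Notch genes had a median of -0.11 (camera 0.0164, estimated 0.571), of which Notch4 (-0.35 ± 0.09) alone fell over the list alone.

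Proliferation genes at E18.5 were all above control (32 of 32) with a median of 0.56 (camera 4.95e-10, estimated 0.571), while 0 passed over the list alone. It was uneven between arrays: exposed arrays 1 and 3 had proliferation scores of 10.6 and 10.8 and the lowest position scores (-0.538 and -0.553), while exposed arrays 2 and 4 (10.1 and 9.44) lay within the control range (9.37 to 10.2). The position score contains proliferation genes, so the 2 scores are not independent. The exact permutation p of the proliferation score was 0.2 (n = 4 and 4). Rrm1, a ribonucleotide reductase subunit, differed by 0.50 ± 0.22 and Cdc20 by 0.58 ± 0.25. Alveolar type 2 genes lay below control in 19 of 20 cases with a median of -0.34 (camera 1.39e-07, estimated 0.571), among them Lamp3 (-0.58 ± 0.23) and Cd36 (-0.45 ± 0.16). All 17 glucocorticoid response genes lay below control, with a median of -0.38 (camera 1.87e-05, estimated 0.571), and Cebpd differed by -0.87 ± 0.38. Oxidative phosphorylation genes had a median of 0.14 with 38 of 40 above control (camera 0.00014, estimated 0.644).

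Immune and early response lists at E18.5 were lower as well. Immediate early genes had a median of -0.32 (camera 4.74e-05, estimated 0.571), with Egr2 at -0.35 ± 0.12 and Jun at -0.36 ± 0.13. Neutrophil genes had a median of -0.37 (camera 0.000129, estimated 0.571), inflammatory cytokine genes -0.28 (camera 0.000141, estimated 0.571), monocyte and dendritic cell genes -0.16 (camera 0.000195, estimated 0.487) and macrophage genes -0.20 (camera 0.00137, estimated 0.571). MHC class II genes lay below control in 10 of 10 cases with a median of -0.21 (camera 0.000496, estimated 0.487), and Ctss (-0.50 ± 0.13) fell over the list alone. Xenobiotic response genes (median -0.07, camera 0.152), oxidative stress genes (median -0.04, 0.425) and metal response genes (median -0.01, 0.955) did not pass; Cyp1a1 differed by 0.04 ± 0.16.

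The sexes of the samples were uneven at E18.5. Xist, transcribed from the inactive X, was high in 4 of 4 control arrays and in 1 of 4 exposed arrays, and Y-linked genes were high in the other 3. Xist averaged 12.64 ± 0.28 in control and 7.29 ± 3.54 in exposed lungs (-5.35 ± 1.44, adjusted p 0.612). A fit with the sex score therefore rests on 1 exposed array at this stage. In it Serpina6 passed at 1.96 (adjusted p 0.0225), and 19 lists passed in place of 22, of which 13 were shared; 9 were lost and 6 were new. Among the lists no longer past the threshold were oxidative phosphorylation, MHC class II, glucocorticoid response and Notch; heart muscle genes turned from below control to above it and passed.

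**Figure D2:**
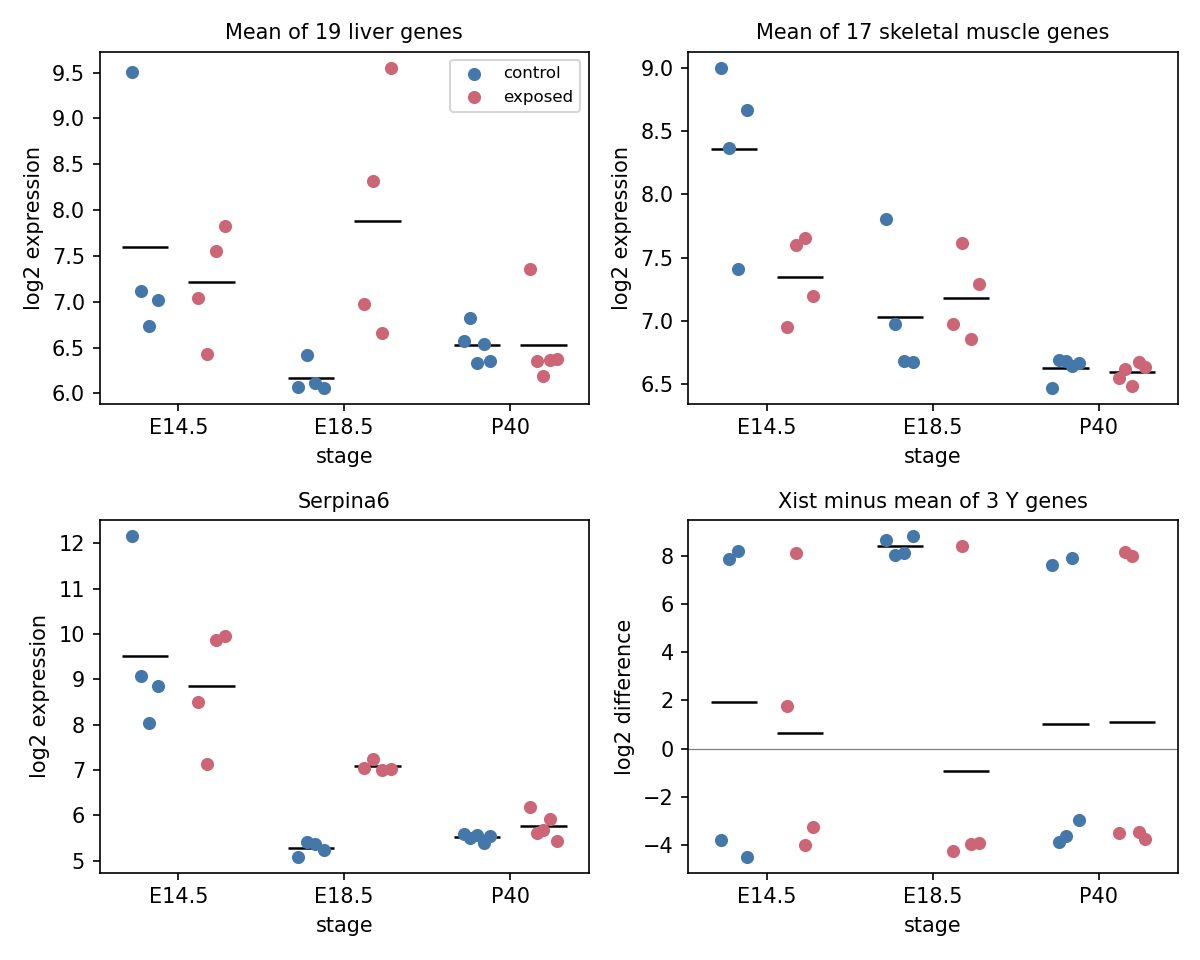
Points are arrays at E14.5, E18.5 and P40, control and exposed side by side, lines are group means, and the y axes are log2 values of the liver score (19 genes), the skeletal muscle score (17 genes), Serpina6, and Xist minus the mean of 3 Y-linked genes. At E18.5 the liver score of the exposed arrays runs from 6.66 to 9.55 against 6.06 to 6.42 in control, while Serpina6 stays at 7.08 ± 0.11 in the exposed arrays.

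At P40 the comparison addressed young adult lungs exposed before and after birth. Matrix genes lay higher and cholesterol synthesis genes lower in exposed lungs, by small amounts, and no gene passed by limma (0 higher, 0 lower). Unadjusted p was under 0.05 for 866 genes, where 0.05 of the tested genes is 832. With the arms rearranged, 34 of 100 splits, the real one included, gave at least as many. Both limma with trend and robust moderation and the fit of all 26 arrays called 0. The smallest p-values belonged to neuritin (Nrn1), at 8.71 ± 0.20 in control and 8.01 ± 0.23 in exposed lungs (-0.70 ± 0.13, n = 5 and 5, adjusted p 0.904), Acsm1 (-0.57), and Pi16, a gene of adventitial fibroblasts (-0.50 ± 0.10). Serpind1 (-0.54), Hook2 (-0.35), Ckmt1 (-0.33) and keratin 18 (Krt18, -0.36 ± 0.08) were lower by point estimate; Scube2 (0.83 ± 0.17), Hs6st3 (0.57), Gria3 (0.43), Nuak1 (0.42) and Epha1 (0.30) were higher.

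Camera called 19 lists at P40, 9 higher and 10 lower; the smallest adjusted p with estimated correlation was 0.447, and fry called 0. Collagens and matrix genes had a median of 0.20 with 28 of 35 above control (camera 2.51e-09, estimated 0.447) and 0 passing over the list alone; Col6a3 differed by 0.74 ± 0.22, fibronectin (Fn1) by 0.57 ± 0.17 and Col6a2 by 0.32 ± 0.11. Fibroblast genes had a median of 0.17 (camera 2.81e-05, estimated 0.447); Mfap4 (0.39 ± 0.10), a microfibril protein shared with the elastic fibre list, rose and Pi16 fell over the list alone. Cholesterol and fatty acid synthesis genes lay below control in 21 of 24 cases with a median of -0.14 (camera 3.05e-07, estimated 0.447), and 5 fell over the list alone, among them Dhcr7 (-0.34 ± 0.09), Fdps (-0.41 ± 0.11) and Fdft1 (-0.33 ± 0.09). Mesothelial genes, of the lung's outer lining, were below control in 13 of 13 cases with a median of -0.29 (camera 3.95e-06, estimated 0.643), and Aldh1a2 (-0.64 ± 0.18) fell over the list alone.

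Proliferation genes at P40 had a median of -0.27 with 31 of 32 below control (camera 2.99e-05, estimated 0.711), heart muscle genes -0.31 (camera 5.98e-05, estimated 0.711) and alveolar type 2 genes -0.10 with 19 of 20 below control (camera 0.00199, estimated 0.447). Interferon genes had a median of 0.09 (camera 8.63e-05, estimated 0.447). Oxidative stress genes had a median of -0.09 (camera 0.0463, estimated 0.656); Hmox1 (-0.48 ± 0.13) and Me1 (-0.31 ± 0.08) fell over the list alone. Immediate early genes were called higher (camera 0.0279, estimated 0.711) although their median was -0.02; Fos differed by 0.79 ± 0.26. Xenobiotic and metal response genes did not pass (camera 0.721 and 0.135); Cyp1a1 differed by 0.25 ± 0.24 (adjusted p 0.929) and Nqo1 by -0.14 ± 0.13.

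**Figure D3:**
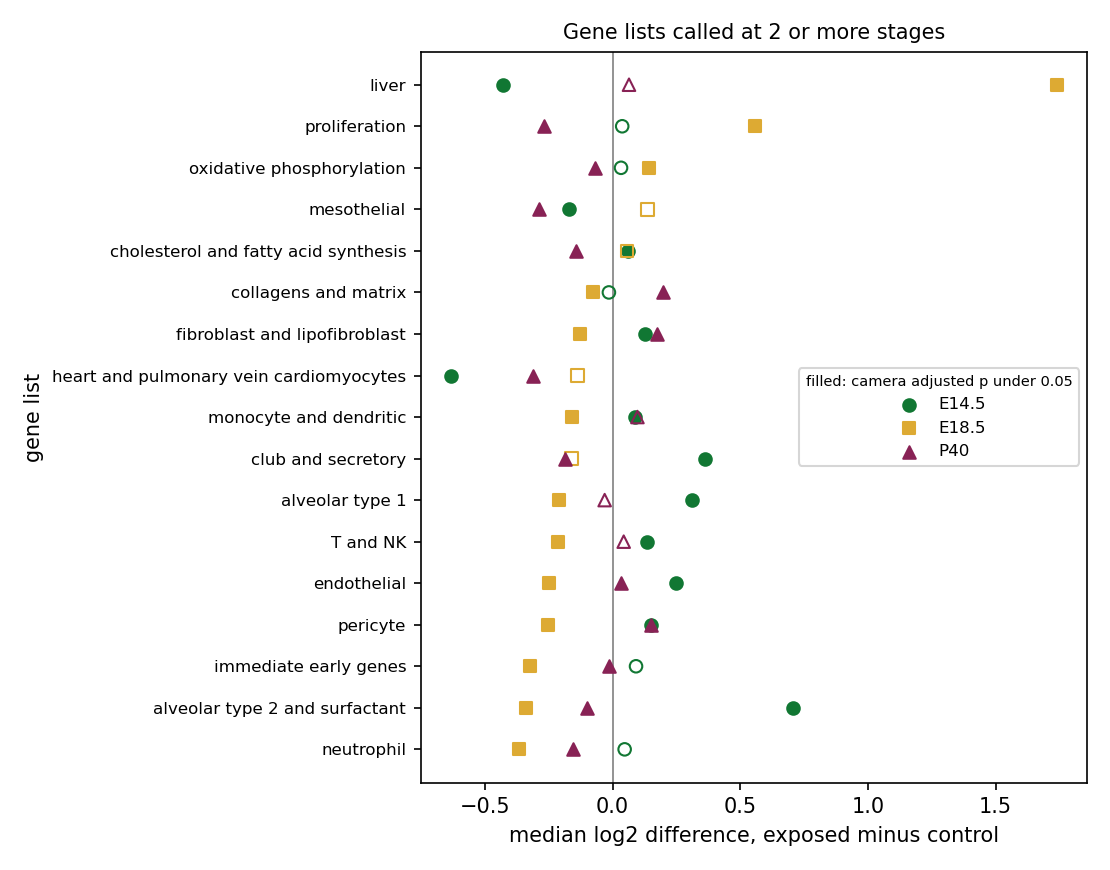
The x axis is the median log2 difference, exposed minus control, of each gene list on the y axis, with 1 point per stage; filled points have a camera adjusted p under 0.05 at the preset correlation, and lists are those called at 2 or more stages. The endothelial medians are 0.25 at E14.5, -0.25 at E18.5 and 0.03 at P40, and those of the alveolar type 2 list are 0.71, -0.34 and -0.10.

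Whether exposure acted differently at E18.5 and E14.5 was tested as an interaction, and here endothelial genes moved from above control to below it. By limma 17 genes passed, 2 higher and 15 lower. Cyyr1 had the smallest adjusted p, at -1.02 ± 0.14 (adjusted p 0.00463, probe set 17331692): exposed lungs were above control at E14.5 (8.98 ± 0.09 and 9.52 ± 0.16) and below it at E18.5 (11.16 ± 0.18 and 10.69 ± 0.17, n = 4 each). It passed with any 1 of the 26 arrays left out; taking the mean of its 2 probe sets gave -0.61, which did not pass. VE-cadherin (Cdh5), the junction protein of endothelium, changed by -0.42 ± 0.08 (adjusted p 0.0419).

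Other vascular genes changed the same way between E14.5 and E18.5. They were the lectins Clec1a (-1.18 ± 0.21, adjusted p 0.0322) and Clec14a (-0.82 ± 0.15, 0.0322), Nostrin (-1.09 ± 0.20, 0.0322), which binds endothelial nitric oxide synthase, and the BMP receptor Acvrl1 (-0.95 ± 0.18, 0.0349). The hypoxia factor Epas1 (-1.20 ± 0.24, 0.0419), angiotensin-converting enzyme Ace (-1.90 ± 0.38, 0.0442) and the phosphatase Ptprb (-0.93 ± 0.19, 0.0443) completed these. Ace averaged 7.45 ± 0.14 in control and 8.59 ± 0.81 in exposed lungs at E14.5, and 12.18 ± 0.41 and 11.42 ± 0.49 at E18.5. Falls were also seen in Trpc1 (-0.73 ± 0.13, 0.0322), Alox5ap (-0.99 ± 0.19, 0.0397), Scn7a (-1.22 ± 0.24, 0.0419) and C87198 (-1.36 ± 0.27, 0.0443). Alox5ap also has 2 probe sets, whose mean gave -0.63 and did not pass.

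The 2 genes that changed upward were Cfi (1.57 ± 0.28, adjusted p 0.0322), which did not differ at E14.5 (8.35 ± 0.34 and 8.33 ± 0.07), and the mesenchymal transcription factor Twist1 (1.53 ± 0.27, 0.0322). Twist1 averaged 8.49 ± 0.58 in control and 7.14 ± 0.27 in exposed lungs at E14.5, and 6.69 ± 0.12 and 6.88 ± 0.22 at E18.5. In control lungs Cyyr1 and Ace rose from E14.5 to E18.5, and Cfi and Twist1 fell. Their interactions thus ran opposite to normal development, and some exposed arrays lay toward the other fetal stage. The part of developmental position was not tested for single genes. The number of genes ran from 1 without E14.5 control array 1 to 126 without E18.5 exposed array 4 and was 642 with array weights, and Cyyr1 was the 1 gene left with the sex score as covariate. The standard errors of this interaction also draw on the spread of the P40 arrays, which are not compared. Leaving out a single P40 array gave 9 to 17 genes, and a fit of the fetal arrays alone was not run.

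**Figure D4:**
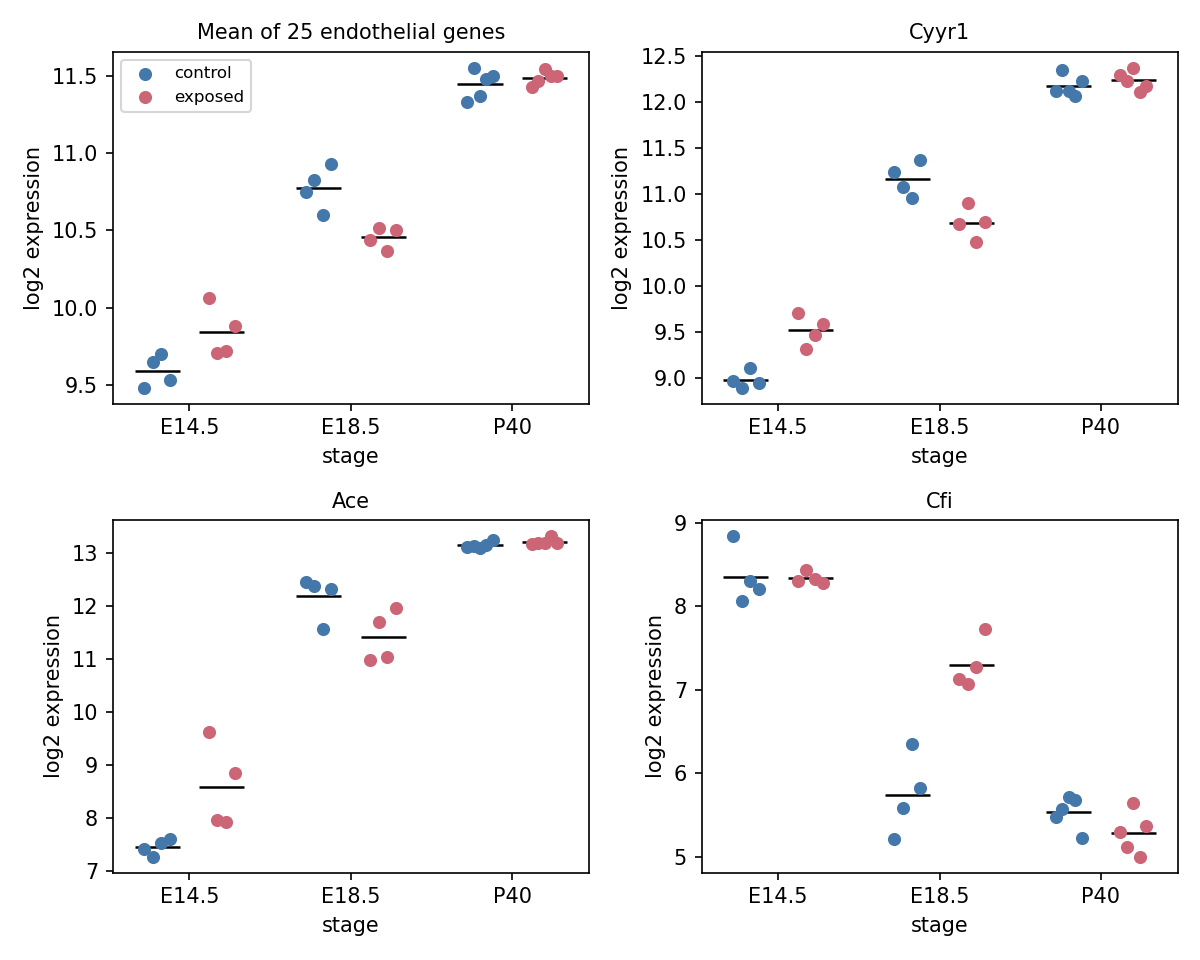
Points are arrays by stage and arm, lines are group means, and the y axes are log2 values of the endothelial score (mean of 25 genes), Cyyr1, Ace and Cfi. The endothelial score of exposed arrays lies above control at E14.5 (9.84 ± 0.17 against 9.59 ± 0.10), below it at E18.5 (10.46 ± 0.07 against 10.78 ± 0.14) and beside it at P40 (11.49 ± 0.04 against 11.45 ± 0.09).

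The endothelial list was the group whose exposure difference changed between E14.5 and E18.5 by camera at both correlations and by fry. Of 25 genes, 24 had a negative interaction, the median was -0.48, 2 fell over all genes tested and 17 fell when adjusted over the list alone (camera 1.17e-23, estimated 0.018, fry 0.000835). It was the 1 list of 33 called by camera, 12 upward and 21 downward, that held with estimated correlation. With the liver and muscle scores in the fit that call was lost (estimated 0.284), while the median was -0.43 and camera at the preset correlation still called the list (4.06e-12). The endothelial score compared between arms gave an exact permutation p of 0.0286 at E14.5 and at E18.5, the smallest these designs allow, and 0.389 at P40 (n = 4, 4 and 5 per arm); adjusted over the 30 score tests these were 0.286, 0.286 and 0.729, and none passed.

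Alveolar type 2 genes had a negative interaction in 20 of 20 cases, with a median of -1.23 and 15 falling over the list alone (camera 3.96e-16, estimated 0.214). Most of these genes rose from E14.5 to E18.5 in control lungs, and some exposed arrays lay toward the other fetal stage. The part of developmental position was not tested for this list. Lamp3 differed by -1.89 ± 0.43 (adjusted p 0.0941) and Muc1 by -1.29 ± 0.30 (0.0941). In the alveolar type 1 list the median was -0.61 with 13 falling and 1 rising over the list alone (camera 6.6e-10, estimated 0.214). Pericyte genes had a median of -0.43, with 4 falling over the list alone (camera 4.55e-07, estimated 0.214). The other lists with more than 10 members passing over the list alone were tissues around the lung: liver genes had a median of 2.12 with 15 rising (camera 3.78e-11, estimated 0.252), and skeletal muscle genes 1.14 with 13 rising (camera 9.71e-10, estimated 0.214).

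Between P40 and E18.5 unadjusted p was under 0.05 for 2252 genes, where 0.05 of the tested genes is 832. With the arms rearranged, 10 of 100 arrangements, the real one included, gave at least as many. The exposure difference of Cfi changed by -1.80 ± 0.26 (adjusted p 0.00672, probe set 17402572), the only gene that passed by limma. The count was 96 without E18.5 exposed array 4, 21 without E18.5 control array 3 and 440 with array weights, Cfi among them each time. Cfi averaged 5.74 ± 0.47 in control and 7.30 ± 0.30 in exposed lungs at E18.5, and 5.53 ± 0.20 and 5.29 ± 0.25 at P40. Camera called 22 lists, 17 upward and 5 downward, none with estimated correlation (smallest adjusted p 0.207). Proliferation genes had a median of -0.86 with all 32 negative and 18 falling over the list alone (camera 6.88e-14, estimated 0.593), led by Plk1 (-1.07 ± 0.32). Endothelial genes had a median of 0.29 with 6 rising over the list alone (camera 6.64e-11, estimated 0.207), and pericyte genes 0.43 with 8 rising (camera 2.55e-07, estimated 0.207). Collagens and matrix genes had a median of 0.30 with 4 rising and 1 falling over the list alone (camera 5.63e-07, estimated 0.556), and Col6a2 differed by 0.51 ± 0.14.

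Between P40 and E14.5 keratin 18 (Krt18), of simple epithelia, was the 1 gene that passed, with a change of -0.65 ± 0.10 (adjusted p 0.0357, probe set 17315245). It averaged 10.22 ± 0.09 in control and 10.51 ± 0.13 in exposed lungs at E14.5, and 10.96 ± 0.09 and 10.60 ± 0.09 at P40; centring the arrays gave -0.61 and ended the call, as did leaving out any 1 of 18 of the 26 arrays, while 55 genes passed without E14.5 control array 3. By unadjusted p under 0.05 there were 1095 genes. Skeletal muscle genes had a median of 1.10 with 5 rising over the list alone (camera 1.26e-12, estimated 0.225), alveolar type 2 genes -0.86 with 6 falling (camera 6.66e-10, estimated 0.571), and club cell genes -0.99 with 0 passing (camera 2.91e-06, estimated 0.571). Endothelial genes had a median of -0.20 with 1 falling over the list alone (camera 6.35e-05, estimated 0.571).

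A difference shared by the 3 stages was not found in any gene: limma called 0, with and without trend and robust moderation. Unadjusted p was under 0.05 for 687 genes, where 0.05 of the tested genes is 832. Rearranged arms gave a median of 645, and 47 of 100 arrangements, the real one included, gave at least 687. The retinaldehyde reductase Dhrs3 (-0.28 ± 0.07), Kcnj2 (-0.43 ± 0.10), Wnk4 (-0.25 ± 0.06) and Cym (0.90 ± 0.22) were among those with the smallest p (adjusted p 0.995). Camera called 19 lists, 5 higher and 14 lower, of which none held with estimated correlation (smallest 0.668). Heart muscle genes had a median of -0.36 with 27 of 29 below control (camera 4.61e-09, estimated 0.738) and skeletal muscle genes -0.31 (camera 0.000104, estimated 0.738). Retinoic acid genes had a median of -0.10 (camera 0.00776, estimated 0.668), and Dhrs3 in that list fell over the list alone. Across the 16635 genes the exposure differences correlated at a Pearson r of -0.04 between E14.5 and E18.5, 0.00 between E14.5 and P40 and -0.18 between E18.5 and P40; genes are not independent replicates.

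Normal development was read from the control lungs. From E14.5 to E18.5 by limma 4347 genes rose and 5177 fell (1460 and 1025 at a fold of 2). The phosphate transporter Slc34a2 of alveolar type 2 cells rose by 7.62 ± 0.17, from 5.67 ± 0.47 to 13.29 ± 0.14 (n = 4 and 4), Retnla by 7.92 ± 0.27, Lyz1 by 7.32 ± 0.19, Scgb1a1 by 7.16 ± 0.50 and Lamp3 by 6.43 ± 0.10 (adjusted p 4.11e-14). Falls were seen in embryonic haemoglobin Hbb-y (-5.42 ± 0.14, adjusted p 3.71e-12), Serpina6 (-4.25 ± 0.61), Afp (-4.23 ± 0.62), Alb (-3.98 ± 0.81) and embryonic myosin Myh3 (-3.23 ± 0.60).

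Camera called 26 lists for this step, 21 upward and 5 downward, and with estimated correlation none passed (smallest 0.124), while fry called 39. Of 20 alveolar type 2 genes 19 rose and 1 did not pass, with a median of 3.64 (camera 4.63e-16, estimated 0.124); Sftpb rose by 4.42 ± 0.09. In the ciliated list 22 of 23 rose (median 2.49, camera 5.5e-13, estimated 0.321), and in the endothelial list 23 of 25 (median 1.10, camera 4.28e-11, estimated 0.198). Of the alveolar type 1 genes 17 rose and 1 fell (median 2.25, camera 4.28e-11, estimated 0.124), Ager by 4.31 ± 0.10. Club cell genes rose in 15 of 17 cases (median 2.80, camera 1.31e-08, estimated 0.124). All 32 proliferation genes fell (median -1.56, camera 1.06e-09, estimated 0.447), Ccne1 among them (-2.40 ± 0.19). Of 17 glucocorticoid response genes 14 rose, 1 fell and 2 did not pass (median 1.55, camera 1.58e-05, estimated 0.329). Liver genes fell in 11 of 19 cases (median -1.35, camera 0.0205, estimated 0.663) and skeletal muscle genes in 14 of 17 (median -1.53, camera 0.0158, estimated 0.591).

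From E18.5 to P40 by limma 3301 genes rose and 4035 fell (824 and 715 at a fold of 2). The J chain of secreted antibodies (Jchain) rose by 5.68 ± 0.21, from 4.05 ± 0.36 to 9.72 ± 0.44 (n = 4 and 5), Atp6v0d2 by 5.74 ± 0.21, Cyp2b10 by 5.03 ± 0.13 (adjusted p 1.83e-11) and the MHC class II gene H2-Ab1 by 3.93 ± 0.23. Cyp1a1, which passed in no exposure comparison, rose by 3.77 ± 0.24. The imprinted gene Dlk1 fell (-4.92 ± 0.14, adjusted p 3.52e-11), as did Hif3a (-4.85 ± 0.16), Zim1 (-4.78 ± 0.15), Rian (-4.75 ± 0.21), fibrillin 2 (Fbn2, -4.43 ± 0.16) and Igf2 (-3.64 ± 0.11).

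Camera called 28 lists between E18.5 and P40, 16 upward and 12 downward, and 2 held with estimated correlation. These were the imprinted growth genes, of which 13 of 15 fell (median -1.71, camera 7.97e-11, estimated 0.00664), and the MHC class II genes, all 10 of which rose (median 1.93, camera 3.59e-10, estimated 0.043). B and plasma cell genes rose in 18 of 19 cases (median 2.67, camera 1.64e-14, estimated 0.0793) and T and NK cell genes in 22 of 24 (median 1.83, camera 2.45e-12, estimated 0.18). Proliferation genes fell in 28 of 32 cases (median -1.68, camera 8.81e-11, estimated 0.403), ribosomal protein genes in 29 of 38 (median -0.36, camera 7.92e-08, estimated 0.18), and elastic fibre genes in 10 of 13 with 1 rising (median -1.03, camera 5.96e-05, estimated 0.18). Of 13 xenobiotic response genes 7 rose, 1 fell and 5 did not pass (median 0.81, camera 0.000675, estimated 0.0793).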

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

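The liver and endothelial patterns tested below were themselves found in these results. The sex and exposure tests of the liver difference were chosen after the results had been seen. So were the sex and tissue dilution tests of the endothelial change, the liver and muscle covariates, and the splits of the fit with the liver covariate.

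Liver genes at E18.5. Liver genes were higher in exposed lungs, with a median of 1.74 and a liver score of 7.88 ± 1.33 against 6.17 ± 0.17. One hypothesis is liver tissue carried along at dissection. Across the 19 liver genes the E18.5 difference followed each gene's slope on the liver score at E14.5 (Spearman rho 0.8123). Alb (7.29 to 11.60) and Afp (5.97 to 9.59), abundant products of fetal liver, differed most. The score contains each of the 19 genes, and any shared rise of liver transcripts could rank them alike. Rho therefore does not single out dissection. The sex of the fetuses cannot be told apart: the median kept 123.6% of its size with the sex score in the model (1.74 to 2.15), but only exposed array 2 shares the high Xist of the 4 controls, so that fit rests on 1 array. An effect of exposure itself cannot be told apart from unequal dissection or sex: the exact permutation p of 0.02857 is the smallest that 4 against 4 arrays allow, and no label records dissection or litter. Serpina6 did not follow the liver score, staying near 7.08 ± 0.11 in exposed arrays whose liver scores ran from 6.66 to 9.55.

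Endothelial genes between E14.5 and E18.5. The median exposure difference of the list changed by -0.48 (adjusted p with estimated correlation 0.01798). With a sex effect alike at each stage in the model it kept 97.02% of its size, so such an effect does not account for it. E14.5 exposed array 1, with neither sex marker high, entered that model with a score of 1.78. With the developmental position score the list's median kept 99.57%, but the endothelial score's interaction went from -0.57 ± 0.11 to -0.46 ± 0.12. The position score rests on different genes at each stage and entered with 1 slope for all stages. That fit therefore cannot exclude a difference in maturity, and some exposed arrays at both fetal stages lay toward the other stage. With the liver and muscle scores together the list's median kept 89.38%, from -0.48 to -0.43. The endothelial score's interaction was then -0.58 ± 0.14 (p 0.000515), and the adjusted p of the list with estimated correlation rose to 0.284. In that fit the list's median was smaller, the median error of its genes larger (0.22 against 0.18) and their correlation 0.275 against 0.259; these parts were not separated, so dilution by these tissues cannot be told apart, nor can a sex effect at E18.5 alone, where 1 exposed array has the sex pattern of the controls. Rearranged groups gave a p as small in 1 of 100 arrangements, which was the real one (0.000327, next 0.00243). Only this list, the 1 that passed in the real groups, was compared. The smallest p over all lists was not taken in each arrangement, so chance is not excluded.

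Genes whose exposure difference changed between E14.5 and E18.5 were Ace (-1.899), Acvrl1 (-0.9457), Alox5ap (-0.9939), C87198 (-1.359), Cdh5 (-0.4239), Clec14a (-0.8234), Clec1a (-1.179), Cyyr1 (-1.016), Epas1 (-1.198), Gm13315 (-1.469), Ica1 (-0.6323), Nostrin (-1.089), Ptprb (-0.9267), Scn7a (-1.216) and Trpc1 (-0.7286), all downward, and Cfi (1.571) and Twist1 (1.534) upward. Between P40 and E18.5 it was Cfi (-1.804), and between P40 and E14.5 Krt18 (-0.6483). Cyyr1 between E14.5 and E18.5 and Cfi between P40 and E18.5 kept their calls with each of the 26 arrays left out in turn; other named genes between E14.5 and E18.5 lost theirs in 9 or more of the 26, and Krt18 in 18.

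Rearranging the arms at E14.5 gave at least as many passing genes in 35 of 35 splits (0 real, highest other 5), at least as many lists in 4 of 35 (23 real, highest other 24), and at least as many genes at unadjusted p under 0.05 in 4 of 35 (1269 real, highest other 1989). At E18.5 the same counts were 2 of 35 for genes (1 real, highest other 760), 18 of 35 for lists (22 real, 32) and 7 of 35 for unadjusted p (1219 real, 4188). For P40 they were 100 of 100 for genes (0 real, 52), 20 of 100 for lists (19 real, 28) and 34 of 100 for unadjusted p (866 real, 2267). The split with 760 genes points to a structure of the E18.5 samples other than the arms.

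For the change between E14.5 and E18.5, at least as many genes passed in 5 of 100 arrangements (17 real, highest other 740), lists in 1 of 100 (33 real, 32) and genes at unadjusted p in 16 of 100 (1589 real, 3654). Between P40 and E18.5 these were 9 of 100 (1 real, 1390), 34 of 100 (22 real, 29) and 10 of 100 (2252 real, 4288). Between P40 and E14.5 they were 11 of 100 (1 real, 102), 34 of 100 (17 real, 32) and 14 of 100 (1095 real, 2167). The common difference gave 100 of 100 (0 real, 3), 42 of 100 (19 real, 29) and 47 of 100 (687 real, 2839). Arrangements with 740 and 1390 genes also point to a structure of the samples other than the arms, and numbers of passing genes like the real ones can arise by chance in these comparisons.

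For development in control lungs, E14.5 to E18.5 gave 1 of 35 splits for genes (9524 real, highest other 10), 10 of 35 for lists (26 real, 35) and 1 of 35 for unadjusted p (10272 real, 4557). From E18.5 to P40 they were 1 of 100 (7336 real, 4283), 21 of 100 (28 real, 33) and 1 of 100 (8529 real, 6690); the arrangement with 4283 genes points to a structure of the samples, since a random arrangement can still hold the stages unevenly. With the liver score as covariate at E18.5 the real arms gave more genes than any other split, 1 of 35 (834 real, highest other 314). Only in the real arms did the liver scores not overlap, so the other splits are not a like comparison.

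Single arrays stood apart from their group in 14 of 180 groups examined, where chance at 1 in 20 gives 9, so most of these can be chance. In the tissue and stage scores they were: liver score 9.507 in E14.5 control array 1 (others 6.74 to 7.12), 6.423 in E18.5 control array 2 (6.06 to 6.11) and 7.359 in P40 exposed array 1 (6.19 to 6.37); skeletal muscle score 6.470 in P40 control array 1 (6.64 to 6.69); erythroid score 9.945 in E14.5 control array 1 (8.30 to 8.43); developmental position -0.05024 in E18.5 control array 3 (0.269 to 0.327). Liver and erythroid genes were high in the same E14.5 control array, and leaving it out turned the direction of both lists at E14.5 (adjusted p 0.0423 and 0.0302). Single genes standing apart were Trpm6 5.669 in E14.5 control array 4 (5.90 to 5.95), Gnb3 6.050 in E14.5 exposed array 2 (5.78 to 5.79), Cyp1b1 7.515 in E18.5 control array 1 (6.57 to 6.69), Hmox1 9.643 in the same array (8.84 to 8.97) and Scube2 11.17 in P40 exposed array 3 (10.74 to 10.85).

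The remaining ones were sex markers: Xist was 12.37 in E14.5 exposed array 2 (5.35 to 6.39) and 12.59 in E18.5 exposed array 2 (5.32 to 5.66), and the sex score there was 8.414 (-4.23 to -3.91). These are the arrays with high Xist in groups where the others had low Xist.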

How the results depend on the processing

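Exposure at E14.5, E18.5 and P40. The fit of all 26 arrays called 24 genes at E14.5 (5 higher, 19 lower) in place of 0, and at E18.5 Cfi in place of Serpina6. Leaving out the dimmer 0.5 of genes called 0 at E18.5 in place of 1, since Serpina6 is among them. The liver covariate, added after the data were seen, called 834 at E18.5 (439 higher, 395 lower). Camera with estimated correlation and fry each called 0 lists at E14.5, 0 at E18.5 and 0 at P40. The muscle covariate, also added afterwards, left 6 lists at E14.5 (3 higher, 3 lower). Among them were the heart and skeletal lists, which make up that score and are forced apart by it.

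Change between E14.5 and E18.5. In place of 17 genes, there were 7 with no filter (2 higher, 5 lower), 642 with array weights (213 higher, 429 lower), 7 with centred arrays (2 higher, 5 lower, a larger share higher than the 2 of 17), 1 with every probe set tested (0 higher, 1 lower), 1 with the sex covariate (0 higher, 1 lower), 2 with a replicate block (0 higher, 2 lower), 48 with the liver covariate (6 higher, 42 lower) and 2 with the muscle covariate (1 higher, 1 lower). Estimated correlation and fry each left 1 list. The replicate numbers were not taken as pairs, since the labels give them no meaning and not every same-number pair of arrays correlated above 0.1 (0 of 4 at E14.5, 2 of 4 at E18.5 with a highest r of 0.577, 4 of 5 at P40). An array correlated best with its own number in 0, 2 and 1 cases. At P40 the same-number pairs correlated at 0.0762 to 0.178, against a mean of -0.0346 for the other pairs. Shared handling by number is therefore not excluded at P40, nor for single pairs at E18.5. The cause of the other shifts was not tested.

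Other comparisons. Between P40 and E18.5, 0 genes were left without the dimmer 0.5 of genes and 440 passed with array weights (213 higher, 227 lower). Between P40 and E14.5, 0 were left with no filter, with quantile normalization again, with centred arrays, with the mean of all probe sets, with every probe set tested and with a replicate block. Estimated correlation and fry each called 0 lists in both, and 0 for the common difference. For development, a fold of 1.5 as well left 5142 genes (2676 higher, 2466 lower) from E14.5 to E18.5 and 3285 (1691 higher, 1594 lower) from E18.5 to P40; estimated correlation left 0 lists and 2 lists (1 higher, 1 lower).

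Lists that turned direction and passed before or after the turn, with the adjusted camera p after it. At E14.5 with the muscle covariate: FGF signalling and branching tip genes 0.342, platelet and megakaryocyte 0.732, heart and pulmonary vein cardiomyocytes 0.000162 and liver 0.543; without control array 1: erythroid and haemoglobin 0.0302 and liver 0.0423. At E18.5 with the sex covariate: collagens and matrix 0.690 and heart 0.0287; with the liver covariate: basal and squamous 0.0225, mesothelial 0.00252 and liver 0.203. At P40 with the muscle covariate: heart 0.923; without exposed array 1: liver 0.00698. Between E14.5 and E18.5 with the liver covariate: mesothelial 0.939, erythroid 0.00767, platelet 0.939 and liver 0.313; with the muscle covariate: heart 1.77e-07; without E14.5 control array 1: erythroid 0.682. Between P40 and E14.5 without E14.5 control array 1: liver 0.631. The liver score is the mean of the liver list, so with the liver covariate that list's mean difference vanishes by construction. The muscle score holds the heart and skeletal lists, which must then differ in opposite directions on average. Turns of liver genes under the liver covariate and of heart genes under the muscle covariate are therefore fixed by the fit. Over all arrays left out in turn, the p of the lists so turned ran from 0.0174 to 0.603 (erythroid, E14.5), 0.00326 to 0.529 (liver, E14.5), 0.00698 to 0.910 (liver, P40), 0.00360 to 0.682 (erythroid, between E14.5 and E18.5) and 0.00204 to 0.631 (liver, between P40 and E14.5).

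Leaving out each array in turn. Genes ran from 0 to 1 at E14.5 (1 without control array 3), 1 to 5 at E18.5 (5 without exposed array 2) and 0 to 0 at P40. Between E14.5 and E18.5 they ran from 1 (without any of E14.5 control 1 and 4, exposed 1, E18.5 control 1, 2 and 4, exposed 1) to 126 (without E18.5 exposed 4), with 113 without E14.5 control 3, 100 without E14.5 exposed 3 and 81 without E18.5 control 3. Between P40 and E18.5 they ran from 1 to 96 (without E18.5 exposed 4), and between P40 and E14.5 from 0 to 55 (without E14.5 control 3), with Krt18 not called in 18 of the 26. The common difference stayed at 0, and development ran from 8829 to 9601 and from 6507 to 8033. Lists ran from 17 to 25, 21 to 29, 14 to 20, 26 to 34, 17 to 25, 13 to 19, 11 to 23, 24 to 28 and 27 to 30 in the order of the report. No named gene that passed in the main fit or in an alternative turned direction there (0). Sign changes of named genes that passed in neither were not counted. The endothelial list kept its camera call between E14.5 and E18.5 in every alternative. Dim genes on an array lie near background, where differences are compressed.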

Other observations

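With the liver score in the model, 834 genes separated exposed from control lungs at E18.5, where the plain comparison gave 1. No other of the 35 splits of the same 8 arrays gave more than 314. A hypothesis is that unequal liver content hides a wider exposure difference at this stage, but this fit cannot decide it. The liver scores of the arms did not overlap (control 6.06 to 6.42, exposed 6.66 to 9.55), while those of every other split did. Across exposed arrays 3, 1, 2 and 4 liver scores (6.66, 6.98, 8.32 and 9.55) and position scores (-0.553, -0.538, -0.133 and 0.334) rose together. The covariate can therefore also take up developmental position. It was chosen after the data were seen, and sex was also uneven between the arms. The hypothesis needs lungs of known sex and litter, dissected free of liver.

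Serpina6 and Cfi lay higher in all 4 exposed arrays at E18.5 than in any control array, with less spread (7.08 ± 0.11 and 7.30 ± 0.30) than the liver score (7.88 ± 1.33). Both were high in the E14.5 lungs of both arms (9.52 and 8.35 in control), so at E18.5 the exposed lungs lie between the E14.5 and the E18.5 control values.

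E14.5 exposed array 1 had neither marker of sex high: Xist 6.39, and a mean of 4.60 over 3 Y-linked genes. The other arrays had 1 of the markers high. E14.5 exposed array 1 entered the fits with the sex covariate at a score of 1.78, and it had the highest endothelial score at E14.5 (10.1). Without it 1 gene passed in the change between E14.5 and E18.5, as without some other fetal arrays.

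The 24710 probe sets outside the tested genes gave 0 passing in each exposure comparison; at unadjusted p under 0.05 there were 869 at E14.5, 1649 at E18.5 and 1075 at P40. The smallest adjusted p, 0.195, was in the change between P40 and E18.5.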
